A study of Gasterosteus aculeatus with 12 samples.

How the data were processed

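Gill DNA of 12 male stickleback was cut with MspI, and fragments of 170 to 350 bp, adaptors included, were treated with bisulfite and sequenced, per the labels. Per the submitters' processing notes, CASAVA 1.8.2 and Bismark were used. The version of Bismark and the genome build were not given in the sources used here. The authors deposited 2 tables of counts, 1 of reads that cover each cytosine and 1 of methylated reads, with a column per fish. They listed 16342843 positions on 24 sequence names. No methylated count was above its coverage count. The highest positions of the chromosomes fit the lengths of the stickleback build gasAcu1, and this was taken as the build for the windows only. Reads lost by the authors' alignment or filters cannot be seen in these counts, and PCR copies were not separated, so intervals cover counting error only.

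Both cytosines of a CpG were summed where neighbouring positions were listed, which gave 10991588 sites. In odd runs, 49831 positions were left single. Lambda phage and mitochondrial positions were kept out of the tests and used as unmethylated controls, which was decided after the tables were seen. A site was tested with 10 or more reads in each fish. Sites at most 100 bp apart were joined, and clusters of 3 or more sites were tested on their summed counts. A level is methylated reads over all reads in percent, and a group level is the mean of its fish. No 2 fish were alike: the fewest sites that differed between any pair was 239692. Replicates are numbered as in the labels' descriptions, and the columns of the deposited tables carry other numbers in 3 groups: replicates 1, 2 and 3 are columns MM1, MM3 and MM4, MF3, MF4 and MF5, FM1, FM2 and FM3, and FF2, FF3 and FF4. Each column is a separate fish, per the labels, so the p-values measure the spread between fish.

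Each site or cluster was tested with a quasi-binomial logistic model on the counts. The Pearson dispersion was moderated across units by the method of limma, with a floor of 1, and tested with a likelihood-ratio F test. All groups shared 1 dispersion with 8 residual degrees of freedom. All marine against all freshwater fish was fitted with 10. A unit was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of 10 points or more. Where nothing differs, an unadjusted p under 0.05 would be found in a share of about 0.05 of units. Mean levels were compared by two-sided exact permutation tests, and windows by Fisher's exact test. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.

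The test was tested on simulated reads with the coverage, levels and spread of the real sites and 200 changed sites. No simulated fish was shifted over all its sites, as some real libraries were, so the shares found here may differ in these fish. Changes of 60 points were cut short where they would have passed the ends of the scale. For all marine against all freshwater fish, 5.50% of changes of 20 points, 58.0% of 40 points and 87.0% of 60 points were found among 288446 sites in 12 fish, with 13 false calls beside the 174 true calls at 60 points. In 11 fish, 54.0% of 40 points and 95.0% of 60 points were found among 702128 sites. Between groups of 3 in 12 fish, 0% of changes of 20 points were found, 8% (MM against FF) to 20.5% (MF against MM) of 40 points and 51.5% to 63.0% of 60 points. The highest number of false calls was 29, beside 116 true calls, for MF against FF at 60 points. FM against FF had 8 beside 21 at 40 points, and MF against MM 2 beside 0 at 20 points. In these cases the false share was above that allowed by the adjusted p. The other comparisons of 3 with 3 had 0 false calls at 20 points. The real counts of comparisons of 3 with 3 in 12 fish, 1 to 9 sites, lie within this range, 0 to 29. They may therefore include false calls. In 11 fish 0% of 40 points and 24.5% (FM against FF) to 62.0% (MF against MM) of 60 points were found between groups of 3 or 2.

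The comparisons, tests and rule for named units were fixed before the data were examined. The rule took the 10 called clusters with the largest difference whose fish do not overlap between groups, and the 3 called sites with the largest difference for both same-water comparisons and the interaction. It was applied in the same way to the 11 fish. Of the 28 clusters called in 11 fish between populations, 23 had no overlap of fish. An annotation of the build was not used here, so promoters, gene bodies and the planned gene lists were not analysed here. Other settings fixed in advance were coverage of 5 or 20 reads, sites of very high coverage left out, a difference of 25 points, reads thinned to 10, limma on logit levels, edgeR, a replicate block, each fish left out in turn, separate strands, 2 groups in the fit, water as a covariate and a cluster gap of 300 bp. Sets of 11, 10 and 9 fish, another prior of the dispersion and centred levels were added after the data were seen.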

Results

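DNA methylation was measured in the gills of male three-spined stickleback (Gasterosteus aculeatus), a fish with sea-living and lake- or river-living populations. The assay was reduced-representation bisulfite sequencing, in which an enzyme that cuts at CCGG selects CpG-rich fragments and bisulfite turns unmethylated cytosine into uracil. There were 12 fish in 4 groups of 3. Marine fish were kept in marine water (MM) or moved to fresh water for 4 days (MF). Freshwater fish were kept in fresh water (FF) or moved to marine water for 4 days (FM). The calls per fish, summed over all listed cytosines, ranged from 34584624 in FF replicate 1 to 116755440 in FF replicate 2. With 10 or more reads in every fish, 288446 CpG sites were tested, and they formed 37358 clusters of 3 or more sites. The median coverage of a tested site lay between 28 reads in FF replicate 1 and FM replicate 3 and 100 reads in FM replicate 2. Positions are those of the deposited tables, in which neighbouring genes are not listed, so each site is given by chromosome and position.

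FM replicate 3 stood apart from the other 11 fish. Its mean level over the tested sites was 78.2%, against 47.2% to 56.2% in the others. All reads were methylated at 64.9% of its sites, against at most 3.16% of sites in any other fish. Its correlation with the other fish across sites was 0.380 to 0.407, while the other 11 fish correlated with each other at 0.868 to 0.971. Lambda phage DNA, commonly added as an unmethylated control and listed in the deposited tables, was called methylated in 36.6% of its calls (95% Wilson interval 36.5% to 36.7%), and in 0.138% to 0.497% in the other fish. Counts below are therefore given for all 12 fish, as planned, and for 11 fish without it, a choice made after the control was seen. All 12 are separate individuals, per the labels. Without FM replicate 3, 702128 sites and 74482 clusters had 10 reads in each of the 11 fish.

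**Figure D1:**
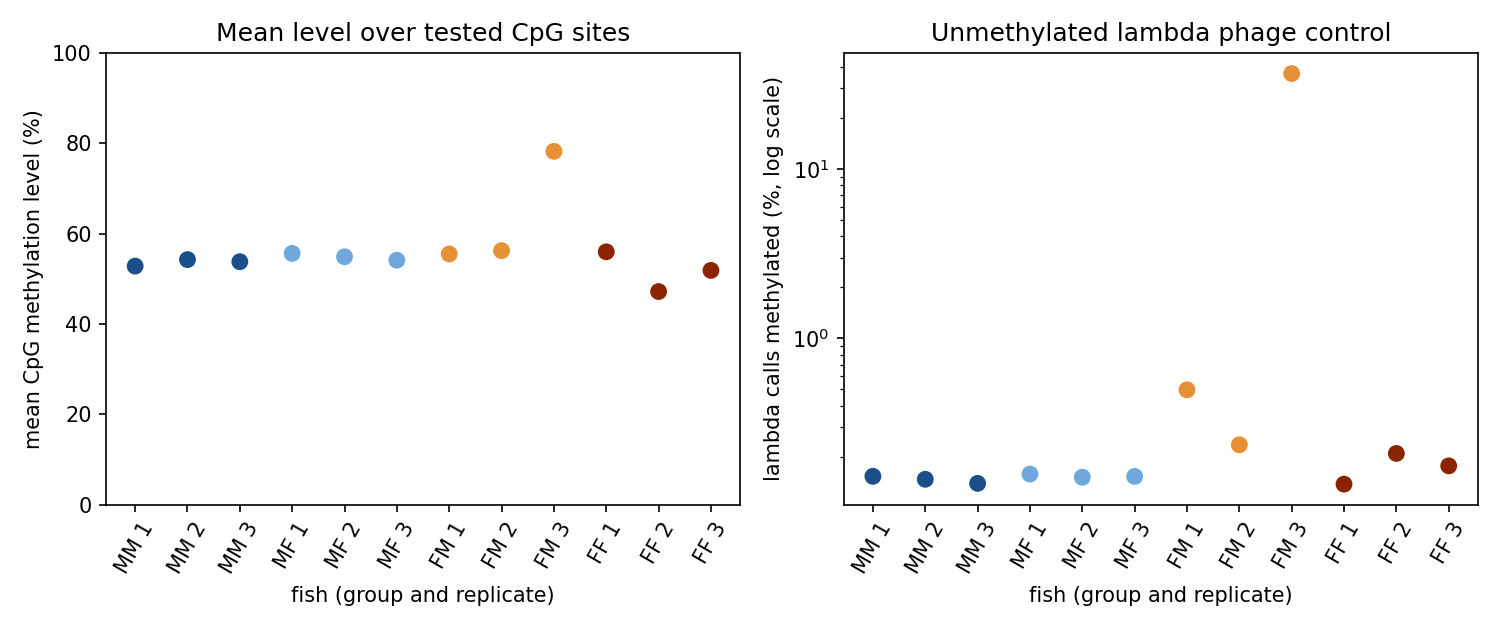
Each point is 1 fish, coloured by group. The left panel gives the mean methylation level over the tested CpG sites in percent, and the right panel the percent of lambda phage calls that were methylated, on a log axis. FM replicate 3 lies at 78.2% and 36.6%.

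The difference in mean methylation level did not pass the test in any comparison. The mean level was 53.6% ± 0.737 (SD, n = 3) in MM, 54.9% ± 0.749 (SD, n = 3) in MF, 63.3% ± 12.9 (SD, n = 3) in FM and 51.7% ± 4.40 (SD, n = 3) in FF. Without FM replicate 3 the FM mean was 56.3% ± 0.517 (SD, n = 2). The difference was 1.95 points for MM minus FF (two-sided exact permutation p = 0.6), 1.26 points for MF minus MM (exact permutation p = 0.2) and 11.6 points for FM minus FF (exact permutation p = 0.2). MM minus FM gave −9.70 points (exact permutation p = 0.1), with each FM fish above each MM fish, and −2.34 points without FM replicate 3 (exact permutation p = 0.2). MF minus FF gave 3.20 points (exact permutation p = 0.4). With 3 fish against 3 the smallest p this test allows is 0.1, so no difference between groups of 3 could pass. All marine minus all freshwater fish gave −3.25 points (exact permutation p = 0.662), and 0.980 points without FM replicate 3 (exact permutation p = 0.654). FF replicates 2 and 3 had the lowest levels, 47.2% and 51.9%, and FF replicate 1 had 56.0%. Without FM replicate 3 and FF replicate 2, MM minus FF turned to −0.154 points.

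The comparison of all marine with all freshwater fish asked which sites differ between the populations in either water. Short stretches of CpG sites differed strongly. Of the 28 clusters called in 11 fish, 17 were more methylated in marine fish and 11 less. The 10 named were chosen for a large difference without overlap of fish, and 9 of them were more methylated in marine fish. In 11 fish, a cluster of 11 sites on chromosome IV, 20252493 to 20252624, had a level of 68.4% ± 3.83 (SD, n = 6) in marine and 2.16% ± 2.04 (SD, n = 5) in freshwater fish, with 374 to 2684 reads per fish. Over the 10 named clusters of this comparison the reads per fish ranged from 75 to 4217. A cluster of 21 sites on chromosome IX, 1110880 to 1111137, had 55.0% ± 5.00 (SD, n = 6) in marine and 8.12% ± 4.49 (SD, n = 5) in freshwater fish. A cluster of 10 sites on chromosome XV, 14353556 to 14353675, had 75.3% ± 2.97 (SD, n = 6) against 30.4% ± 4.34 (SD, n = 5). On the unplaced sequences, 8 sites at 5030060 to 5030204 had 62.9% ± 5.79 (SD, n = 6) against 18.8% ± 6.53 (SD, n = 5).

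Other clusters differed less evenly between fish. On chromosome VIII, 18 sites at 13989488 to 13989748 had 57.0% ± 18.9 (SD, n = 6) in marine and 4.54% ± 2.06 (SD, n = 5) in freshwater fish, and the marine fish ranged from 32.2% to 71.7%. On chromosome VII, 7 sites at 8867838 to 8867934 had 78.8% ± 4.24 (SD, n = 6) against 27.6% ± 14.7 (SD, n = 5). On the unplaced sequences, 17 sites at 26557516 to 26557613 had 86.0% ± 2.33 (SD, n = 6) against 35.4% ± 24.3 (SD, n = 5). On chromosome IV, 7 sites at 31235658 to 31235758 had 70.1% ± 2.31 (SD, n = 6) against 29.8% ± 11.2 (SD, n = 5), and 8 sites at 9853133 to 9853287 had 49.0% ± 12.5 (SD, n = 6) against 12.9% ± 3.97 (SD, n = 5). The only one of these 10 clusters that was lower in marine fish had 5 sites on chromosome IV, 12875607 to 12875692, with 33.9% ± 10.6 (SD, n = 6) against 72.7% ± 4.08 (SD, n = 5). It lies in the window set around Eda, a signalling gene of bony plate development, and a single site in it had 0% in all marine fish.

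**Figure D2:**
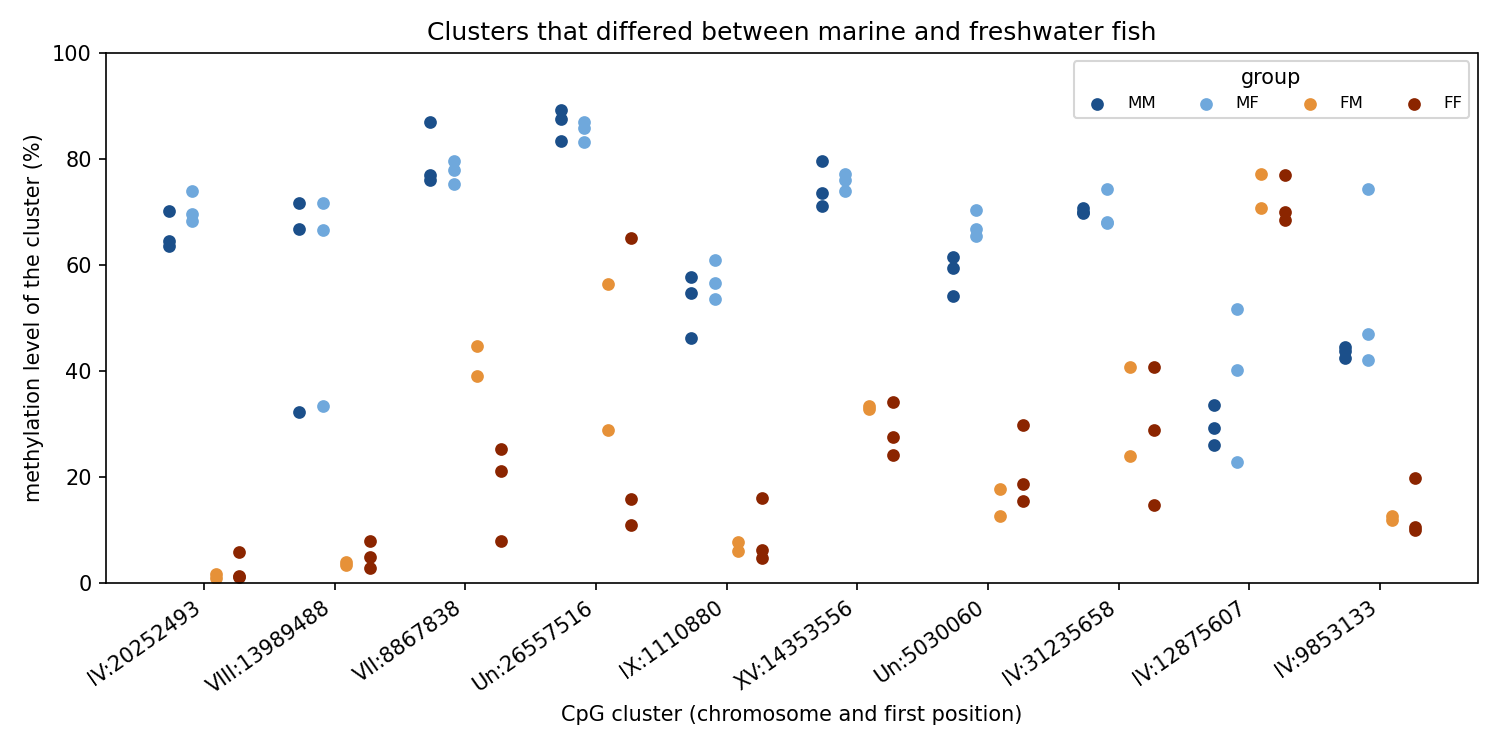
Methylation level in percent of the 10 named clusters in each of 11 fish, with 1 point per fish coloured by group. The clusters were chosen among those whose fish do not overlap between populations, so the separation follows from the choice. In 9 of the 10 clusters the marine fish lie above the freshwater fish, and in the cluster on chromosome IV from 12875607 they lie below them.

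In the quasi-binomial test with Benjamini-Hochberg adjustment, 25 sites passed in 12 fish, 14 of them higher in marine fish, and 134 in 11 fish, 88 of them higher. Of the clusters, 1 passed in 12 fish and 28 in 11 fish, 17 of these higher in marine fish. The direction of the clusters turned with the fish used: without FF replicate 2 as well, 22 were higher and 35 lower, and without FF replicates 2 and 3, 32 and 55. At single sites the quasi-binomial test called 77 higher and 46 lower without FM replicate 3 and FF replicate 2, and 93 and 44 without FF replicate 3 as well. With limma 5 sites were higher and 12 lower in 12 fish, and 194 and 88 in 11 fish, where the quasi-binomial test with its dispersion prior taken from sites of 5 to 95%, a choice made after the data were seen, gave 363 and 134. The cluster called in 12 fish holds 6 sites on chromosome I, 21650266 to 21650336, with 51.1% ± 3.39 (SD, n = 6) in marine and 83.2% ± 8.09 (SD, n = 6) in freshwater fish (adjusted p = 0.0090). Its site at 21650295 had 0% in all 6 marine fish and 85.3% ± 8.18 (SD, n = 6) in freshwater fish. The adjusted p of the cluster on chromosome IV from 20252493 was 4.8e-06 and that of the cluster on chromosome XV 1.9e-05. Of the 134 called sites, 100 had a mean level of 10 to 50%, as did 14.9% of all tested sites, and none had 90% or more. This mean is taken over both populations, so a large difference itself puts a site in the middle, and nothing follows about where differences lie. With edgeR, 1 site and no cluster passed in 12 fish, where 573 of 37358 clusters had an unadjusted p under 0.05, below the share that chance gives.

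Calls gathered in chromosome windows fixed in advance around loci known to differ between marine and freshwater stickleback. In 11 fish, 32 of 8369 tested sites in the 4 windows were called, 3.82 per 1000, against 0.147 per 1000 elsewhere (odds ratio 26.1, Fisher's exact p = 6.3e-32). The window at 5 to 6 Mb of chromosome XI held 14 calls, that at 21 to 22 Mb of chromosome I 11, that at 12 to 13 Mb of chromosome IV 5, and that at 5 to 8 Mb of chromosome XXI 2. The enrichment in the chromosome XXI window did not pass (Fisher's exact p = 0.171). In 12 fish 8 of 25 calls lay in the windows (odds ratio 40.5, Fisher's exact p = 2.8e-10), 5 on chromosome XI and 3 on chromosome I, and the windows on chromosomes IV and XXI held 0 calls of the quasi-binomial test. Of the 32 calls in the windows, 28 were sites where 1 population read 2% or less in every fish, and without such sites 4 of 83 calls lay there (Fisher's exact p = 0.018). None of these 4 shared its difference with the nearest tested site. That at 5577284 on chromosome XI had no tested site within 100 bp. At the others the nearest site differed the other way, with signed differences of −14.8, −29.9 and −3.33 points. Neighbouring sites are not independent, so these p-values are too small. The genome build was not given in the sources used here, and the windows assume the build whose chromosome lengths the highest listed positions fit.

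**Figure D3:**
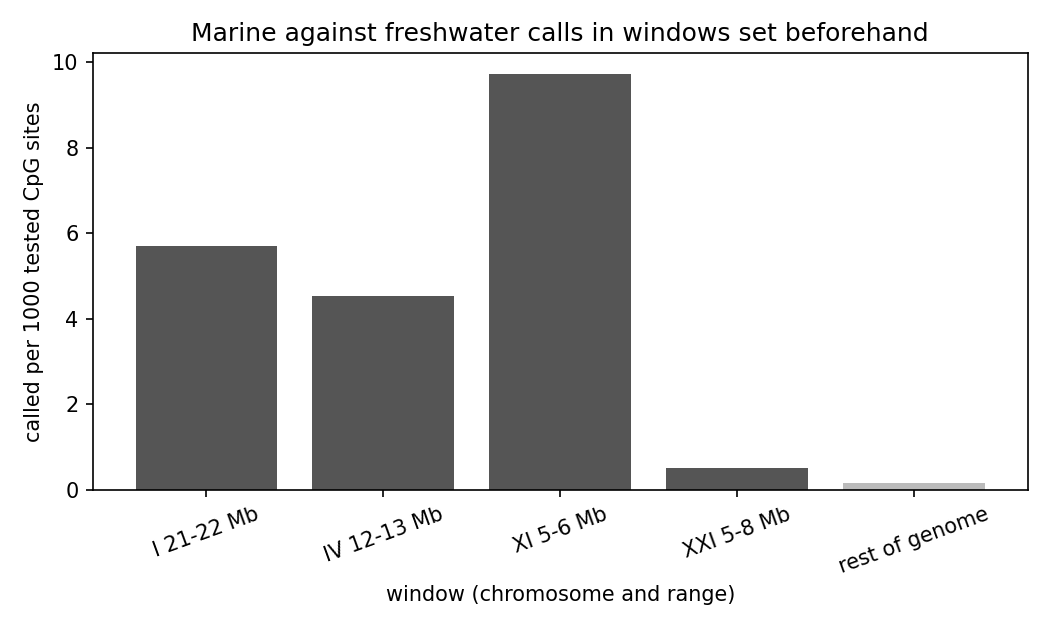
Called sites per 1000 tested CpG sites, marine against freshwater, in 11 fish. The dark bars are the 4 windows by chromosome and range in Mb, and the light bar is the rest of the genome, at 0.147 per 1000.

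The comparison of MM with FF set each population in its own water. In 12 fish 5 sites and no cluster passed, and 2431 clusters (6.51%) had an unadjusted p under 0.05. With limma and with edgeR no cluster passed either. At single sites limma called 1 and edgeR 0, with 2713 of 288446 at an unadjusted p under 0.05, below the share that chance gives. In 11 fish 29 sites and 14 clusters passed, 18 and 9 of them higher in MM, limma called 193 sites, and the other prior gave 1075. The largest cluster difference lay on chromosome I, 22143108 to 22143386, where 19 sites had 4.02% ± 3.28 (SD, n = 3) in MM and 80.6% ± 1.88 (SD, n = 3) in FF, with 27.1% ± 23.3 (SD, n = 2) in FM. On the unplaced sequences, 19 sites at 38275013 to 38275214 had 79.5% ± 0.678 (SD, n = 3) in MM and 10.6% ± 14.7 (SD, n = 3) in FF, while FM had 83.7% ± 0.488 (SD, n = 2). The clusters named above on chromosomes IV from 20252493, VII, IX and XV and on the unplaced sequences from 5030060 were also called, higher in MM. The MM and FF fish are part of the comparison of all marine with all freshwater fish, so this is no separate evidence.

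A further 3 named clusters differed between MM and FF. On chromosome XI, 9 sites at 15366690 to 15366785 had 68.3% ± 14.5 (SD, n = 3) in MM and 11.9% ± 2.20 (SD, n = 3) in FF. On chromosome VI, 21 sites at 14438042 to 14438599 had 57.5% ± 1.75 (SD, n = 3) against 27.1% ± 8.71 (SD, n = 3). On chromosome II, 9 sites at 5417161 to 5417274 had 28.2% ± 2.16 (SD, n = 3) in MM and 59.3% ± 7.62 (SD, n = 3) in FF, with 63.5% ± 4.14 (SD, n = 3) in MF. The counts in 11 fish rested on single fish: without FF replicate 1 they were 77 sites and 5057 clusters, and without MM replicate 3 or FF replicate 3 no site passed the quasi-binomial test. In 12 fish the 5 sites became 11 without FF replicate 1 and 1 without FF replicate 3.

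Few sites were called after marine fish were moved to fresh water. In simulated reads 20.5% of changes of 40 points were found for this comparison in 12 fish and 0% in 11 fish, so a low count does not show that few sites changed. In 12 fish 1 site and no cluster passed, and 547 clusters (1.46%) had an unadjusted p under 0.05, below the share that chance gives. With limma and with edgeR no site and no cluster passed. The site, chosen after its values were seen, lies at 870519 on chromosome XII, with 45.4% ± 10.9 (SD, n = 3) in MM and 0% in all fish of the other groups. In 11 fish no site passed, 27311 (3.89%) had an unadjusted p under 0.05, also below that share, limma called 25, and the other prior gave 53. The clusters were not below it there: 4016 (5.39%) had an unadjusted p under 0.05. Without FF replicate 2 as well, 8.13% of clusters and 4.32% of sites did. The dispersion is estimated over all groups, FM replicate 3 included. Its median over clusters was 9.105 in 12 fish and 3.625 in 11 fish. One cluster passed in 11 fish, with 14 sites on chromosome XVII, 5711341 to 5711498. Its level was 50.6% ± 5.11 (SD, n = 3) in MM and 80.8% ± 1.17 (SD, n = 3) in MF, which are different fish. FM and FF had 79.9% ± 2.44 (SD, n = 2) and 80.6% ± 2.78 (SD, n = 3), so MM alone was low. As many clusters were called in 8 of the 10 groupings of the MM and MF fish, the real one included. Without MF replicate 2 no cluster passed in the remaining 10 fish, and without MF replicate 3, 8 did.

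Moving freshwater fish to marine water gave 3 called sites and no cluster in 12 fish. There 6339 clusters (17.0%) had an unadjusted p under 0.05, and neither limma nor edgeR called a site or a cluster. The 3 calls of sites rested on single fish: without FF replicate 1 there were 1030, and without each of the other FF and FM fish none passed the quasi-binomial test, nor with only the 2 groups in the fit. The sites, chosen after their values were seen, were higher in FM. Those at 38275133 and 38275129 on the unplaced sequences lie in the cluster named above, and the third, at 2579551 on chromosome XV, had 95.6% ± 3.88 (SD, n = 3) in FM and 40.8% ± 7.22 (SD, n = 3) in FF. In 11 fish no site passed, 93168 (13.3%) had an unadjusted p under 0.05, and limma called 29, of which 12 were higher in FM. With the other prior 3763 passed, 3522 of them higher in FM, and without FF replicate 1 as well as FM replicate 3, 13337 passed with the planned prior. Of 9 clusters that passed, 8 were higher in FM.

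The named clusters of this comparison mostly had a low level in FF alone. On chromosome XII, 4 sites at 11161127 to 11161207 had 58.8% ± 5.58 (SD, n = 2) in FM and 13.3% ± 9.15 (SD, n = 3) in FF, against 48.2% ± 1.60 (SD, n = 3) in MM. On chromosome I, 8 sites at 22173927 to 22174038 had 78.4% ± 0.257 (SD, n = 2) against 41.4% ± 14.6 (SD, n = 3), and on chromosome VI, 8 sites at 13877444 to 13877570 had 47.9% ± 4.16 (SD, n = 2) against 15.9% ± 6.53 (SD, n = 3). In 1 cluster FM was lower: 31 sites on the unplaced sequences, 16737463 to 16737894, had 34.9% ± 2.38 (SD, n = 2) in FM and 72.1% ± 6.28 (SD, n = 3) in FF, with 72.0% ± 1.49 (SD, n = 3) in MM. The FF levels include replicates 2 and 3, which were low over all sites. At the same sites, no cluster passed without FF replicate 2, and 10128 passed without FF replicate 1.

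In fresh water, 9 sites were called between MF and FF in 12 fish and 43 in 11 fish. In marine water, 5 and 58 were called between MM and FM. These counts turned with the method: in 12 fish limma called 3 and 4, and edgeR and the fit of only the 2 groups called 0 in both. Of 288446 sites, edgeR had 3564 and 3093 at an unadjusted p under 0.05, below the share that chance gives. In 11 fish limma called 244 and 144, and the other prior gave 15494 and 286. Of the 3 named sites of each comparison in 12 fish, 2 were named in both. At 21650295 on chromosome I both marine groups had 0%, FF had 83.1% ± 5.19 (SD, n = 3) and FM 87.6% ± 11.2 (SD, n = 3). At 19872023 on chromosome IV, MM had 0%, MF 0.327% ± 0.566 (SD, n = 3), FF 75.1% ± 7.46 (SD, n = 3) and FM 92.7% ± 5.78 (SD, n = 3), with 15 to 102 reads per fish. The third site of the fresh water comparison, at 38275129 on the unplaced sequences, had 81.6% to 85.7% in the 3 MF fish and 14.0% ± 14.9 (SD, n = 3) in FF. The third in marine water, at 21341117 on chromosome II, had 0.794% ± 1.37 (SD, n = 3) in MM and 93.5% ± 7.69 (SD, n = 3) in FM. The counts in 11 fish moved with single fish: MF against FF had 19510 sites without FF replicate 1 and none without FF replicate 3, and MM against FM had none without MM replicate 2 or 3. In 12 fish MF against FF had 180 without FF replicate 1 and 1 without FF replicate 3.

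The test of a different response to water in the populations called 0 sites in 12 fish, and limma and edgeR also called 0. There 29619 sites (10.3%) had an unadjusted p under 0.05. In 11 fish it called 0, with 84212 at an unadjusted p under 0.05, and limma called 8, or 12 with centred levels. On simulated reads the quasi-binomial test with its planned prior found 7% of 200 sites with a change of 60 points in 12 fish, and none of those with 40 points. Its count of 0 therefore does not show that no site differed, and other fits were not simulated.

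The changes after both transfers were set against each other over all tested sites. The difference MF minus MM and the difference FM minus FF, which share no fish, correlated across sites at Pearson r = 0.102 (Spearman rho = 0.106) in 12 fish and at r = 0.141 in 11 fish. The jackknife standard error of r over the 12 fish was 0.0995. Their signs were opposite at 42.4% of sites. Sites are not independent replicates, so no p-value is given. The calls of MM against FF and of FM against FF shared 1 site in 12 fish, where simulated unchanged groups against the same FF fish shared 0 and independent lists would share 5.2e-05. These differences correlated across sites at r = 0.385 (covariance 52.4), and in the simulation, where they share only the FF fish, at r = 0.526 (covariance 42.5). In 11 fish r was 0.702 (covariance 62.6), and 0.525 (covariance 26.9) in the simulation. The calls of MM against FF and of MF against MM, which share the MM fish, also had 1 site in common in 12 fish, with opposite signs, where the simulation gave 0 and independent lists 1.7e-05. Their differences correlated at r = −0.245 (covariance −13.9), and at −0.489 (covariance −37.4) in the simulation. In 11 fish r was −0.246 (covariance −14.7), and −0.482 (covariance −21.1) in the simulation. The 3 shared fish of a group cannot be parted into 2 sets of 2 or more fish, so part of an excess may come from the shared fish. The simulated fish had no shift over all sites, whereas FF replicates 2 and 3 were low over all sites. The simulated values are therefore no full baseline for the shared FF fish.

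The shift of moved fish toward the other population was measured at sites called between 2 MM and 2 FF fish and read in the left-out fish. Sites were called in 5 of the 9 combinations, at most 12 in each. In the left-out fish the population difference at these sites averaged 36.7 points, with a range of 25.1 to 49.2. MF differed from the left-out MM fish by −11.0 points in the direction of FF, with a range of −42.1 to 10.0. This mean rested on few sites: it was −42.1 at 1 site and −21.1 at 2 sites, and −2.95, 1.19 and 10.0 at 7, 12 and 5 sites. FM differed from the left-out FF fish by 20.3 points in the direction of MM, with a range of −0.994 to 48.7. The value of FM turned on the FF fish that was left out: it was 20.3 to 48.7 points without FF replicate 1, at 5 to 12 sites, −0.994 without FF replicate 2, at 1 site, and 0.279 without FF replicate 3, at 2 sites. The 12 fish include FM replicate 3. Both ranges cover 0, and no test was made on so few sites. In 11 fish, with sites in 2 combinations, both without FF replicate 1, the shift was 1.32 points for MF and 44.4 for FM. At the 1000 sites of smallest p in each of the 9 combinations, a choice made after the data were seen, the shift of FM was 12.9 points (6.97 to 18.1) in 12 fish and 8.63 points (2.07 to 14.5) in 11 fish, and the population difference 12.8 points and 14.9 points. With FF replicate 1 left out the shift was 6.97 to 7.44 points and the population difference −0.404 to 4.52 in 12 fish, and 2.07 to 2.64 and 0.476 to 7.06 in 11 fish. With FF replicate 2 or 3 left out, both low over all sites, they were 9.82 to 18.1 and 15.8 to 21.4 in 12 fish, and 6.93 to 14.5 and 16.8 to 23.5 in 11 fish. That of MF was −2.38 points (−5.65 to 0.204) and −3.00 points (−7.36 to −0.0884).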

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

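The tests of FM replicate 3, of FF replicate 2 and of the called clusters, and the interval and parts of the test of single called sites, were chosen after the results were seen. Of 44 groups of fish examined, 13 values lay far from the rest of their group. Some of the groups are sites and clusters chosen from these same data, and several values of 1 fish are linked, so no chance rate can be set against this count. FM replicate 3 accounts for 5 of the values. It was the highest of the freshwater fish in mean level (78.2%), in sites with all reads methylated (64.9%), in lambda phage calls (36.6%), in mitochondrial calls (6.52%) and at the cluster on chromosome I from 21650266 (99.1%). The lambda phage and mitochondrial calls are data outside the tested sites, and both were above those of every other fish.

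Lambda phage, commonly added as an unmethylated control, was in FM replicate 3 called methylated in 36.6% of calls and in at most 0.497% in the other fish, which is consistent with failed conversion. One uniform unconverted share is argued against by the mitochondrial calls, which were methylated in 6.52% of calls. Sites under 5% in all other fish read 52.6% on average in this fish. Few source molecules per site may have added to it: at sites of 30 to 70% in the other fish, 12.2% were read at 20 to 80%, or 0.133 of the share in FF replicate 1, a fish of like depth. Failed conversion also raises the level read at such sites, and FF replicate 1 had few methylated lambda phage calls. This comparison therefore cannot tell few molecules from failed conversion. A true difference of this fish was not tested.

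FF replicate 2 read 47.2% on average and 28.8% when sites were weighted by reads. Across clusters its relative coverage fell with the level of the other fish (Spearman rho = −0.616), and the other fish lay between −0.328, in FF replicate 3, and 0.312, which is consistent with over-representation of unmethylated fragments. Admixture of unmethylated DNA would lower all levels by 1 fraction. The ratio to the other fish was 0.960 at sites of 90% or more and 0.674 at sites of 40 to 60%, a gap of 0.286, which argues against it. Cell composition and a true difference of this fish were not tested and stay open.

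For the population calls, a base change at the CpG itself was weighed, since a cytosine replaced by thymine reads as 0%. At the nearest tested site within 100 bp, the median difference in the same direction was 14.7 points over 132 sites (95% bootstrap interval 5.06 to 30.9, drawn by stretches of called sites up to 1000 bp apart), 3.37 points (0.205 to 8.50) at 50 sites where 1 population read 2% or less in every fish and 31.6 points (12.4 to 48.6) at the other 82. With 1 value per stretch the medians were 5.06 (1.41 to 9.50) over all, 5.06 (1.11 to 9.50) over the stretches with sites of the first kind, which a base change may account for, and 7.11 (0.967 to 19.0) over those with the other sites, where the question stays open, as it does over all sites. Parting the sites by whether another called site lay within 1000 bp decides nothing, since this selects neighbours that share the difference or do not: the medians were 50.2 points in stretches and 2.70 points alone for the 82, and −2.47 and 5.06 points for the 50. Without their most different site the 28 clusters kept a median of 25.7 points (13.3 to 33.3), though 6 kept under 10, and among the named clusters that on chromosome IV from 12875607 kept 25.7, and inherited differences in methylation between the populations stay open as a hypothesis.

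The other values that lay apart were those of named clusters and of called sites with the largest differences between all marine and all freshwater fish, which the rule for named units did not cover. In the site on chromosome IV at 19872023 MF replicate 2 had 0.980%, and in that at 23239990 MM replicate 3 had 45.8%. In the site at 19904804 MM replicate 3 had 3.23%. At 19872023 and 19904804 the other marine fish had 0%, with at most 102 and 69 reads in any fish, so very few reads can set such a value apart. FF replicate 2 had 5.77% in the cluster on chromosome IV from 20252493, and MM replicate 2 had 86.9% in that on chromosome VII. FF replicate 3 had 15.9% in the cluster on chromosome IX and 19.8% in that on chromosome IV from 9853133, where MF replicate 2 had 74.3%.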

How the results depend on the processing

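The fish sets, the other prior and the centred levels were chosen after the data were seen. Letters stand for MM against FF (A), MF against MM (B), FM against FF (C), all marine against all freshwater fish (D), MF against FF (E), MM against FM (F) and the interaction (G), and counts are called sites unless clusters are named. The population difference over all fish kept calls under every site alternative, from 1 with edgeR to 739. Of the comparisons of 3 with 3, none kept its count of sites within 1.5 times under all alternatives, and the causes were not tested unless given. Depth limits the calls: thinned to 10 reads, 4 sites were called for D.

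With 5 reads A had 2, C 0, D 59, E 1, F 9 and D clusters 3. With 20 reads A had 3, C 0, D 8, E 4 and F 2. With reads thinned A, B, C, E and F had 0, and D clusters 0. With 2 groups in the fit A, B, C, E and F had 0, A clusters 1 and B clusters 1. With separate strands C had 0 and E 2. With limma A had 1, B 0, C 0, E 3 and D clusters 0. With edgeR A, B, C, E and F had 0, D 1 and D clusters 0.

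In 11 fish A had 29, B 0, C 0, D 134, E 43 and F 58, and clusters A 14, B 1, C 9 and D 28. In 10 fish, also without FF replicate 2, B and C had 0, D 123 and F 27, and clusters A 13, B 2, C 3 and D 57 (22 higher, 35 lower). In 9 fish, also without FF replicate 3, A, B, C, E and F had 0 and D 137, and clusters A 12, B 1, C 10 and D 87 (32 higher, 55 lower). With the prior from levels of 5 to 95%, 11 fish gave A 1075, B 53, C 3763, D 497, E 15494 and F 286, and clusters A 14, B 2, C 9 and D 25. The same in 10 fish gave A 295, B 79, C 55, D 739, E 458, F 504 and G 22, and clusters A 14, B 2, C 5 and D 53. With limma 11 fish gave A 193, B 25, C 29, D 282, E 244, F 144 and G 8, and with centred levels A 228, B 26, C 41, D 325, E 296, F 164 and G 12.

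Leaving out each fish in turn moved A from 1 to 11, B from 0 to 7, C from 0 to 1030, D from 12 to 41, E from 1 to 180, F from 2 to 16 and G from 0 to 1. Clusters moved from 0 to 74 for A, 0 to 1 for B, 0 to 520 for C and 0 to 8 for D. The highest counts of A, C and E came without FF replicate 1, those of D and F without FM replicate 3, and that of B without MM replicate 2. The lowest count of A and E came without FF replicate 3 and that of D without MM replicate 1. C had 0 without each of the other FF fish and without each FM fish.

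Neither the replicate numbers nor the column numbers were seen to pair the fish: deviations of fish with the same replicate number correlated at −0.152 to 0.155, and with the same column number at −0.190 to 0.123. With the number as a replicate block A had 2, C 10398, E 2 and F 9847, and clusters C 48 and D 2. B again had 1, but higher in MF, where that in 12 fish was lower, so the site on chromosome XII was not called. The cause was not tested.

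The mean level of D changed sign in 11 fish (0.980 points) and when weighted by reads (0.975), and that of A in 10 fish (−0.154). Weighted by reads A was 11.9 points, against 1.95, and C 23.2, against 11.6, and in 11 fish C was 4.45. Leaving out each fish gave −0.302 (without FF replicate 2) to 4.10 points (without FF replicate 1) for A, 4.19 (without FM replicate 3) to 15.6 for C and −5.31 (without FF replicate 2) to 0.896 (without FM replicate 3) for D. No mean level passed the exact test under any alternative. The correlation of B with C stayed between 0.0442 and 0.145, and the shift of FM was 44.4 points in 11 fish, in 2 combinations, and −0.683 with 20 reads, against 20.3. Gene promoters, gene bodies and gene lists were not run, since an annotation of the build was not used here.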

Other observations

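The tests of how calls lie in the genome were chosen after the calls were seen, and the counts over other groupings of the fish before. Called sites of marine against freshwater fish in 11 fish were often neighbours in 1 short stretch. At 20 to 21 Mb of chromosome IV 11 of 1113 tested sites were called, all in 1 stretch, and at 1 to 2 Mb of chromosome IX 14 of 2419, in 2 stretches. The hypothesis that calls lie together over 1 Mb was tested on single sites and on stretches. On single sites, 10 windows of 1 Mb held 3 or more calls, and at most 6 did in 1000 draws of as many random tested sites. With called sites up to 1000 bp apart joined, 87 stretches were left, and 3 windows held 3 or more of them, as many as the highest of 1000 draws. All 3 had been set in advance, with 11 stretches on chromosome XI, 10 on chromosome I and 3 on chromosome IV. Gathering over 1 Mb was therefore not shown beyond those windows.

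The calls in the windows set in advance were mostly sites where 1 population read 2% or less in every fish. Over all sites of this kind, inside and outside the windows, the median difference at the nearest tested site was 3.37 points, and a base change at the site stays open. Of 51 such called sites, 28 lay in these windows (Fisher's exact p = 2.0e-40). Of the other 83 called sites, 4 did (Fisher's exact p = 0.018). None of these 4 shared its difference with a nearest tested site within 100 bp, so a base change stays open for them as well. Gathering of sequence differences between the populations stays open as a hypothesis for the windows.

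The level was lower at denser CpG sites in the 4 groups. At the sites with the fewest other listed CpG sites within 100 bp, 0 to 9, MM had 60.4% ± 0.939 (SD, n = 3) and FF 57.6% ± 5.43 (SD, n = 3). At those with 18 to 48 they had 43.1% ± 0.450 (SD, n = 3) and 41.8% ± 3.13 (SD, n = 3). Population calls made up 0.171 and 0.207 per 1000 tested sites, a difference that was not tested.

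Other groupings of the same fish were tested to see how many calls chance gives. For all marine against all freshwater fish, the counts of sites argue against chance as their source. Of 100 groupings drawn from 462, 1 alone, the real one, gave as many in 12 fish (25, at most 3 in the others) and 1 in 11 fish (134, at most 11). A share of 1 of 100 is the smallest this test can give. The other groupings mix both populations, so their counts are not those of fish without a population difference. For clusters, 1 of 100 gave as many in 11 fish (28, at most 2), and 2 of 100 in 12 fish, where the real count was 1 and the highest other 1. For the interaction all 100 gave as many as the real count of 0, and the highest other gave 2. Where the real count is 0, as here and in some cases below, every grouping gives as many by construction, so nothing follows about chance.

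With 3 fish against 3 there are 10 groupings, too few for a share under 0.05. In 12 fish as many sites were called in 1 of 10 for MM against FF (5, highest other 1), 10 for MF against MM (1, highest other 13), 3 for FM against FF (3, highest other 378), 1 for MF against FF (9, highest other 1) and 2 for MM against FM (5, highest other 13). As many clusters were called in all 10 for MM against FF (0, highest other 0), MF against MM (0, highest other 2) and FM against FF (0, highest other 86). In 11 fish as many sites were called in 1 for MM against FF (29, highest other 0), 10 for MF against MM (0, highest other 28) and 1 for MF against FF (43, highest other 1). As many clusters were called in 1 for MM against FF (14, highest other 2) and 8 for MF against MM (1, highest other 3). The highest counts for FM against FF, 378 sites and 86 clusters, set FM replicates 1 and 2 with FF replicate 1 against FM replicate 3 with FF replicates 2 and 3. They point to a difference between these fish or their libraries that does not follow the groups, and its cause was not tested. The highest counts for MF against MM, 13 sites in 12 fish and 28 in 11 fish, were also above the real count. Whether they reflect such a difference was not tested.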
